A study of Mus musculus with 6 samples.

How the data were processed

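Liver RNA from 6 mice (Mus musculus, wild type) was measured by RNA-seq. Per the labels' protocols, feeding on the HFHC diet began at 6 weeks of age and lasted 16 weeks, and DDK or vehicle was given over the last 4 of those weeks. The labels name the diet and the compound only by these abbreviations, and the series title calls DDK a limonoid. Per the labels' protocols, livers were snap frozen, RNA was isolated with an RNeasy Plus kit, and 1.3 µg of total RNA per library went into the NEBNext Ultra RNA kit, which does not mark strand. The series has 2 groups of 3 mice, DDK and vehicle, and each library was assigned to its group from the treatment label. Sex, strain, cage and sequencing batch were not given in the sources used here.

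The values used were the authors' deposited FPKM (fragments per kilobase of gene length, scaled to library size) for 22173 gene symbols in the 6 libraries. Per the submitters' processing notes the genome build was GRCm38 (mm10). The aligner, the counting program and the gene annotation were not given in the sources used here. It is also not stated how fragments that match several genes were counted, so values of near-identical gene copies (the Mup, Saa, Gsta and Gstm families, ribosomal protein genes with pseudogenes) and of genes that share exons (Ugt1a) or overlap on opposite strands are uncertain in how they are divided among family members.

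Depth was recovered from the FPKM values themselves. Within a library the value of 1 fragment depends only on gene length, and a set of whole gene lengths and whole library totals was found for which 100.0% of the values of the 16573 genes above 0 in any library were whole fragments within 0.01 of a fragment. The other 5600 symbols were listed at 0 in every library. The recovered totals behind the FPKM values were 28756915, 26576291 and 30237490 fragments for DDK replicates 1 to 3 and 36105315, 34172473 and 33963898 for vehicle replicates 1 to 3, and 99.6% of each total fell on listed symbols. For a gene of 2000 bp, 3 fragments correspond to an FPKM of 0.0415 to 0.0564, depending on the library, which covers counting error only. Replicates of a group differed by far more than counting error (chi-square per gene from 23.7 to 165), so none was a repeat sequencing of another library of its group.

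FPKM values are not counts, so the test worked on log2(FPKM + 1) with the values scaled as deposited. Genes with an FPKM of at least 0.5 in at least 3 libraries were kept (10681 genes). DDK was compared with vehicle by limma 3.58.1 in R 4.3.3, with a variance trend on mean expression and Benjamini-Hochberg adjustment over all genes kept, and an adjusted p under 0.05 was the threshold. A fold change is on the log2(FPKM + 1) scale, which understates changes of low genes. Errors given with fold changes are standard errors (SE) from limma, and errors of FPKM values are standard deviations (SD) over 3 livers. For 43 gene lists (pathways, complexes and cell type markers), limma's camera with a preset correlation of 0.01 compared each list with all other genes, with Benjamini-Hochberg adjustment over the 39 lists that had at least 4 genes measured. The mitochondrially encoded genes form 1 of the 43 lists and were not analysed here. Camera with a correlation estimated per list, camera on ranks and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were alternatives. The test, the lists, the rule for named genes and all alternatives except 2 were chosen before the data were examined.

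Named genes were, first, the 10 with the largest fold change in each direction among genes past the threshold with a mean FPKM of at least 1 and no overlap between the groups, leaving out predicted genes and pseudogenes. The second part of the rule was Sdha, Sdhb, Sdhc, Sdhd and Sirt3, which are named by or relate to the series title. The third part was the 4 members with the smallest p in the direction of each list past the threshold, and up to 2 members of each other list described. Not every gene that the rule takes is reported here. Any other gene named was chosen after its values were seen, to say which members a count holds. Gene positions are those of GENCODE M21 on GRCm38, in which 21069 symbols had exactly 1 match.

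Alternatives were other pseudocounts (0.1 and 0.5), no filter and a filter at an FPKM of 1, median-ratio scaling, quantile normalization, rescaling to TPM, removal of the 20 most abundant genes, library weights, the replicate number as a block, each library left out in turn, robust variance moderation, no variance trend, and other thresholds. The 2 added after the data were seen were a correction for gene length (a lowess curve with a span of 0.3 of each library's deviation on log2 length, subtracted) and limma's voom on the recovered whole fragments, which called 4239 genes. The gene test and the list test were tested on simulated data for DDK against vehicle (10722 genes passing the filter). Of the genes given a change, the right direction was called for 11.9% of 67 at 1.5-fold, 50.0% of 64 at 2-fold and 89.4% of 66 at 4-fold, and 0.0572% of 10492 unchanged genes were called. The 1 list given a shift was called, and 0% of 38 other lists were. Genes were simulated independently of each other, so these shares do not measure how often camera calls lists whose genes vary together. The simulation also changed far fewer genes than were called in the data, and gave the groups no difference in scaling or length trend. Its shares of genes called, changed or unchanged, therefore do not carry over to the real comparison. Depth recovery and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.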

Results

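The series asked how the small molecule DDK acts against metabolic dysfunction-associated steatohepatitis, a liver disease in which fat storage is joined by inflammation and scarring. Its title relates DDK to deacetylation of SDHA, the flavoprotein subunit of succinate dehydrogenase, and to mitochondrial redox balance. RNA-seq was available for livers of 3 DDK-treated and 3 vehicle-treated wild-type mice, all fed the HFHC diet. Expression was given as FPKM, with 26576291 to 30237490 fragments behind the DDK libraries and 33963898 to 36105315 behind the vehicle libraries. All results concern transcript levels, so acetylation of SDHA and enzyme activity were not measured here.

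DDK-treated livers had much lower transcript levels of genes of lipid storage, the acute phase, lipid-associated macrophages, and stellate cells and extracellular matrix than vehicle livers, and higher levels of genes of xenobiotic metabolism, respiratory complex I and ribosomal proteins, the last 2 being groups of mainly short genes, which stood higher in general. Cidea, a lipid droplet protein, fell from an FPKM of 104 ± 5.86 to 2.93 ± 2.47 (SD, n = 3 per group). Saa1, an acute phase serum amyloid gene, fell from 1265 ± 881 to 29.9 ± 11.8. Ces2a, a carboxylesterase of drug and lipid metabolism, rose from 78.2 ± 13.4 to 599 ± 80.6. Of 10681 genes tested by limma, 4327 passed an adjusted p of 0.05, 1093 of them higher and 3234 lower in DDK. As deposited, the groups did not overlap for 53.3% of genes, where chance gives 10%. Median-ratio scaling factors were 0.867 to 0.934 in DDK and 1.02 to 1.19 in vehicle libraries, so part of that share can come from the scaling.

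The deposited scaling set the balance of higher and lower genes. The median log2 fold change of all genes was -0.23 as deposited, -0.01 after median-ratio scaling, 0.00 after quantile normalization and -0.44 after rescaling to TPM, and the calls became 1931 higher and 1717 lower, 1886 and 1743, and 628 and 5111. Without the 20 most abundant genes, the counts were 856 higher and 3949 lower. Medians of gene lists are therefore given relative to the median of all genes. Leaving out DDK replicate 1, DDK replicate 2, vehicle replicate 2 or vehicle replicate 3 left 2780, 2345, 2774 or 2350 genes past the threshold, and leaving out vehicle replicate 1 gave 5478. The first principal component held 75% of the variance and separated the groups, with vehicle replicate 1 (14.1) nearer to the DDK livers (-36.4 to -23.6) than vehicle replicates 2 and 3 (36.2 and 40.01).

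**Figure D1:**
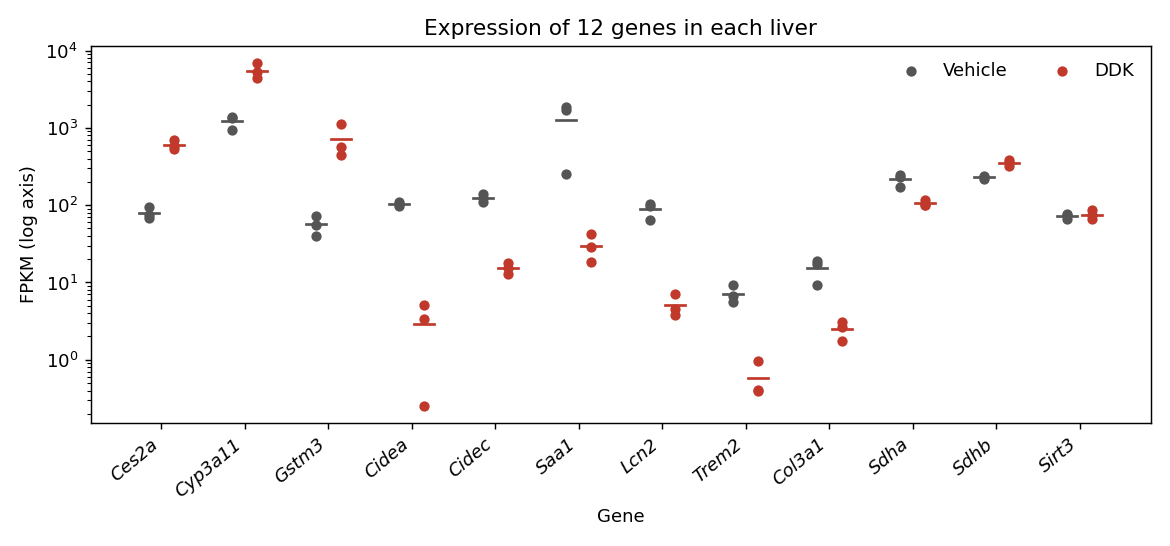
FPKM (log axis) of 12 genes in each of the 6 livers, grey points for vehicle and red points for DDK, with a bar at each group's mean. Cidea, Cidec, Saa1, Lcn2, Trem2 and Col3a1 were lower in all 3 DDK livers than in any vehicle liver, Ces2a, Cyp3a11, Gstm3 and Sdhb were higher, Sdha was lower, and the groups overlapped for Sirt3.

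Genes of xenobiotic metabolism were among the strongest increases. Of 20 measured genes of cytochrome P450 drug metabolism and of the nuclear receptors CAR and PXR, 11 rose and 1 fell, with the same counts adjusted over the list alone. Cyp3a11, a major hepatic drug oxidase and PXR target, rose from an FPKM of 1224 ± 240 to 5507 ± 1257 (log2 fold change 2.16 ± 0.22 SE, adjusted p = 0.000432). Ces2a rose by 2.93 ± 0.16 on the log2 scale (adjusted p = 2.33e-05), Cyp2c55 by 2.56 and Cyp3a25 by 1.38. The member that fell was Ugt1a1, the bilirubin glucuronosyltransferase, from 56.2 ± 20.6 to 6.72 ± 5.23 (log2 fold change -3.02, adjusted p = 0.00124). The list lay 0.76 above all genes in median log2 fold change (camera adjusted p = 3.45e-07, adjusted p = 0.335 with an estimated correlation). The other 8 of the 10 largest increases were the glutathione transferases Gstm3 (3.57 ± 0.32, from 56.2 ± 16.6 to 712 ± 359) and Gsta1 (3.54 ± 0.37), the trefoil factor Tff3 (2.98), the hepcidin gene Hamp2 (2.58), Enho (2.45), which encodes the secreted peptide adropin, and the major urinary protein genes Mup11 (4.07 ± 0.70), Mup7 (3.28 ± 0.89) and Mup16 (2.49). Mup genes are near-identical copies, and their vehicle values were spread widely, Mup7 standing at 48.6, 1193 and 122 in vehicle replicates 1 to 3 against 1533 to 2374 in DDK. Mup7 lost its call without a filter on low values (adjusted p = 0.0844), with robust moderation (0.0955) and without DDK replicate 2 (0.0611) or vehicle replicate 3 (0.0689).

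Genes of fat storage and fat synthesis fell together. Of 21 measured lipid droplet and lipid storage genes, 13 fell and 0 rose, with the same counts adjusted over the list alone (median -0.93 relative to all genes, camera adjusted p = 7.87e-05, adjusted p = 0.335 with an estimated correlation). Cidec, which promotes growth of lipid droplets, fell by 2.95 ± 0.15 on the log2 scale, from an FPKM of 125 ± 14.9 to 15.4 ± 2.43 (adjusted p = 1.80e-05), and Cidea fell by 5.01 ± 0.46 (adjusted p = 0.000292). Pparg, the nuclear receptor that drives fat storage, fell by 1.75, the fatty acid binding protein gene Fabp4 by 2.92 and the monoglyceride lipase gene Mgll by 1.22. Of 22 genes of fatty acid and triglyceride synthesis, 18 fell and 0 rose, and 20 fell adjusted over the list alone. Fasn, fatty acid synthase, fell from 18.0 ± 4.76 to 5.40 ± 0.427 (log2 fold change -1.54, adjusted p = 0.000723), and Acacb (-1.52), Pklr (-1.75) and Fads2 (-1.20) fell too. That list's median lay at -0.74 relative to all genes (camera adjusted p = 5.34e-05, adjusted p = 0.335 with an estimated correlation).

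Other lists of lipid and glucose metabolism were mixed or did not pass. In the list of fatty acid oxidation and PPARA targets, 17 of 32 measured genes fell and 3 rose, with the same counts adjusted over the list alone, including Aldh3a2 (-1.60) and the short-chain acyl-CoA dehydrogenase gene Acads (-1.03). As a list it did not pass (camera adjusted p = 0.0681), but it passed after length correction (0.00815) and by fry (0.00799). After median-ratio scaling 10 of its genes fell and 3 rose, and under TPM 22 fell and 0 rose. Among 24 genes of cholesterol synthesis and uptake, 10 fell and 1 rose (camera adjusted p = 0.209). Of 16 LXR target and cholesterol efflux genes 7 fell and 0 rose (adjusted p = 0.318), Mylip by 1.28 and Npc2 by 1.10. Of 19 bile acid genes 8 fell and 4 rose (adjusted p = 0.986), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.42. Of 18 glucose metabolism genes 8 fell and 0 rose (adjusted p = 0.117), with the glucose-6-phosphatase gene G6pc down by 1.63. Counts in these 4 lists were the same adjusted over the list alone. After median-ratio scaling 5 cholesterol genes fell and 2 rose, and bile acid genes turned to 5 higher and 3 lower. The VLDL and apolipoprotein list moved the other way, with 7 of 17 genes higher and 4 lower, again the same adjusted over the list alone (median 0.53 above all genes, camera adjusted p = 0.00179, adjusted p = 0.335 with an estimated correlation). Apoc3 rose by 1.16, Apoc4 by 1.33, Apoc1 by 1.15 and Tm6sf2 by 1.01. The list's call was lost after quantile normalization (adjusted p = 0.651), by fry (0.0963) and after length correction (0.0998), and that of Apoc1 without DDK replicate 2 (0.05001) or a filter (0.0751).

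Acute phase genes were lower in DDK livers. Of 26 acute phase genes, 18 fell and 2 rose, the same adjusted over the list alone (median -0.39 relative to all genes, camera adjusted p = 0.00531, adjusted p = 0.335 with an estimated correlation). Saa2 fell by 5.07 ± 0.54 on the log2 scale, Saa1 by 4.98 ± 0.64, the lipocalin gene Lcn2 by 3.88 ± 0.23 (adjusted p = 3.27e-05), Steap4 by 2.47 and Orm2 by 2.35. Saa1 and Saa2 are near-identical copies, and Saa1 stood lower in vehicle replicate 1 than in the other vehicle livers in the plot of 12 genes. After median-ratio scaling 11 acute phase genes fell and 2 rose. The 2 members that rose were the hepcidin genes Hamp and Hamp2. Among 22 inflammatory cytokine and chemokine genes, 12 fell and 1 rose (12 and 2 adjusted over the list alone), including the monocyte chemoattractant gene Ccl2 (-1.54) and Cxcl16 (-1.33), but the list did not pass camera (adjusted p = 0.178), which it did after length correction (0.00815). Of 26 interferon response genes 14 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.0109, adjusted p = 0.612 with an estimated correlation), with Ifit3 (-1.13), Gbp2 (-1.17), Oasl1 (-1.41) and Irgm1 (-1.04). That call was lost without vehicle replicate 1 (adjusted p = 0.18), without DDK replicate 3 (0.0531) and with library weights (0.158).

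Macrophage markers were lower as well. Of 18 markers of lipid-associated macrophages, 13 fell and 0 rose, the same adjusted over the list alone (median -0.87 relative to all genes, camera adjusted p = 5.29e-05, adjusted p = 0.335 with an estimated correlation). Trem2, a lipid-sensing receptor, fell from an FPKM of 7.15 ± 1.88 to 0.590 ± 0.330 (log2 fold change -2.35 ± 0.20, adjusted p = 0.000239). Gpnmb fell by 2.88, Mmp12, macrophage elastase, by 2.35 and Anxa2 by 3.04 ± 0.12 (adjusted p = 3.57e-06), and Anxa2 is also made by many other cell types. Of 21 general macrophage and Kupffer cell markers 15 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.000887, adjusted p = 0.612 with an estimated correlation). Lysozyme, Lyz2, fell from 224 ± 77.2 to 38.2 ± 15.4, and the complement gene C1qc (-1.55), Mpeg1 (-1.55) and Itgax (-0.86) fell. Of 9 MHC class II and antigen presentation genes 7 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.0441, adjusted p = 0.612 with an estimated correlation), among them H2-Eb1 (-1.45), H2-Ab1 (-1.29), H2-DMb1 (-1.25) and Cd86 (-0.69). Without vehicle replicate 1 the calls of the macrophage and Kupffer list (adjusted p = 0.0637) and the MHC class II list (0.276) were lost, although 14 of 21 and 5 of 9 genes fell there. The MHC class II call was also lost without a filter (0.0841), after rescaling to TPM (0.104), with library weights (0.272) and without DDK replicate 3 (0.0763).

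Genes of the stellate cell and extracellular matrix list fell, and the cells that made these transcripts were not identified. Of 33 measured genes of stellate cells and extracellular matrix, 23 fell and 0 rose, and 25 fell adjusted over the list alone (median -0.60 relative to all genes, camera adjusted p = 4.45e-05, adjusted p = 0.609 with an estimated correlation). Col3a1, a fibrillar collagen, fell from an FPKM of 15.2 ± 5.30 to 2.49 ± 0.690 (log2 fold change -2.17 ± 0.26, adjusted p = 0.000723). The basement membrane collagens Col4a1 and Col4a2 fell by 1.83 and 1.07, and Sparc fell by 1.34.

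Markers of endothelial, biliary, T and NK, and red blood cells did not pass camera as lists. Of 17 endothelial markers 8 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.0531, fry adjusted p = 0.0421), Plvap by 1.32 and Pecam1 by 1.02. Of 9 cholangiocyte and progenitor markers 1 rose, Krt7 (0.44), and 1 fell, Cd24a (-0.59), also adjusted over the list alone (camera adjusted p = 0.683). None of the 5 measured T and NK cell markers passed limma's test, adjusted over all genes or adjusted over the list alone. Nkg7 stood at a log2 fold change of 0.36 ± 0.32 and Ccl5 at 0.25 ± 0.27. Of 5 red blood cell genes 2 rose, Hba-a1 (0.87) and Hba-a2 (0.74), and 1 fell, Alas2 (-0.51), with 2 and 2 adjusted over the list alone (camera adjusted p = 0.458). The neutrophil, B and plasma cell, and adipose and pancreas lists had 3 measured genes each and were not tested as lists, and in them S100a9 fell (-1.01) and Adrb3 rose (1.12). Leaving out any of DDK replicate 1, vehicle replicate 2 or vehicle replicate 3 ended the calls of Krt7 (adjusted p = 0.0556 to 0.0807, and 0.0795 without DDK replicate 3) and of Cd24a (0.0731 to 0.119, and 0.12 without DDK replicate 2). Those of Alas2 ended without DDK replicate 1 (0.0706), DDK replicate 2 (0.0769) or vehicle replicate 2 (0.074) and after median-ratio scaling (0.259), quantile normalization (0.0815) or length correction (0.0777), and those of Hba-a1 without DDK replicate 2 (0.0646) or vehicle replicate 3 (0.0976), a filter (0.094) or after TPM (0.0542) or length correction (log2 fold change 0.27, adjusted p = 0.431). Of the red blood cell genes 0 rose and 2 fell under TPM, and 0 rose and 1 fell after length correction. Hepatocyte markers lay 0.49 above all genes in median (camera adjusted p = 0.00149, adjusted p = 0.335 with an estimated correlation), with 8 of 21 higher and 3 lower, and 10 and 3 adjusted over the list alone. Albumin, Alb, rose by 0.88, Hal by 1.42, Serpina1c by 0.97 and Arg1 by 0.65. After quantile normalization that list lay at -0.02 relative to all genes (adjusted p = 0.685), and counts there were 4 higher and 5 lower, as under TPM. Alb lost its call without a filter (adjusted p = 0.156) and without DDK replicate 2 (0.0535), while quantile normalization gives the highest gene of every library, here Alb, the same value by construction (adjusted p = 1). Arg1 lost its call after quantile normalization (0.24) and rescaling to TPM (0.0686).

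**Figure D2:**
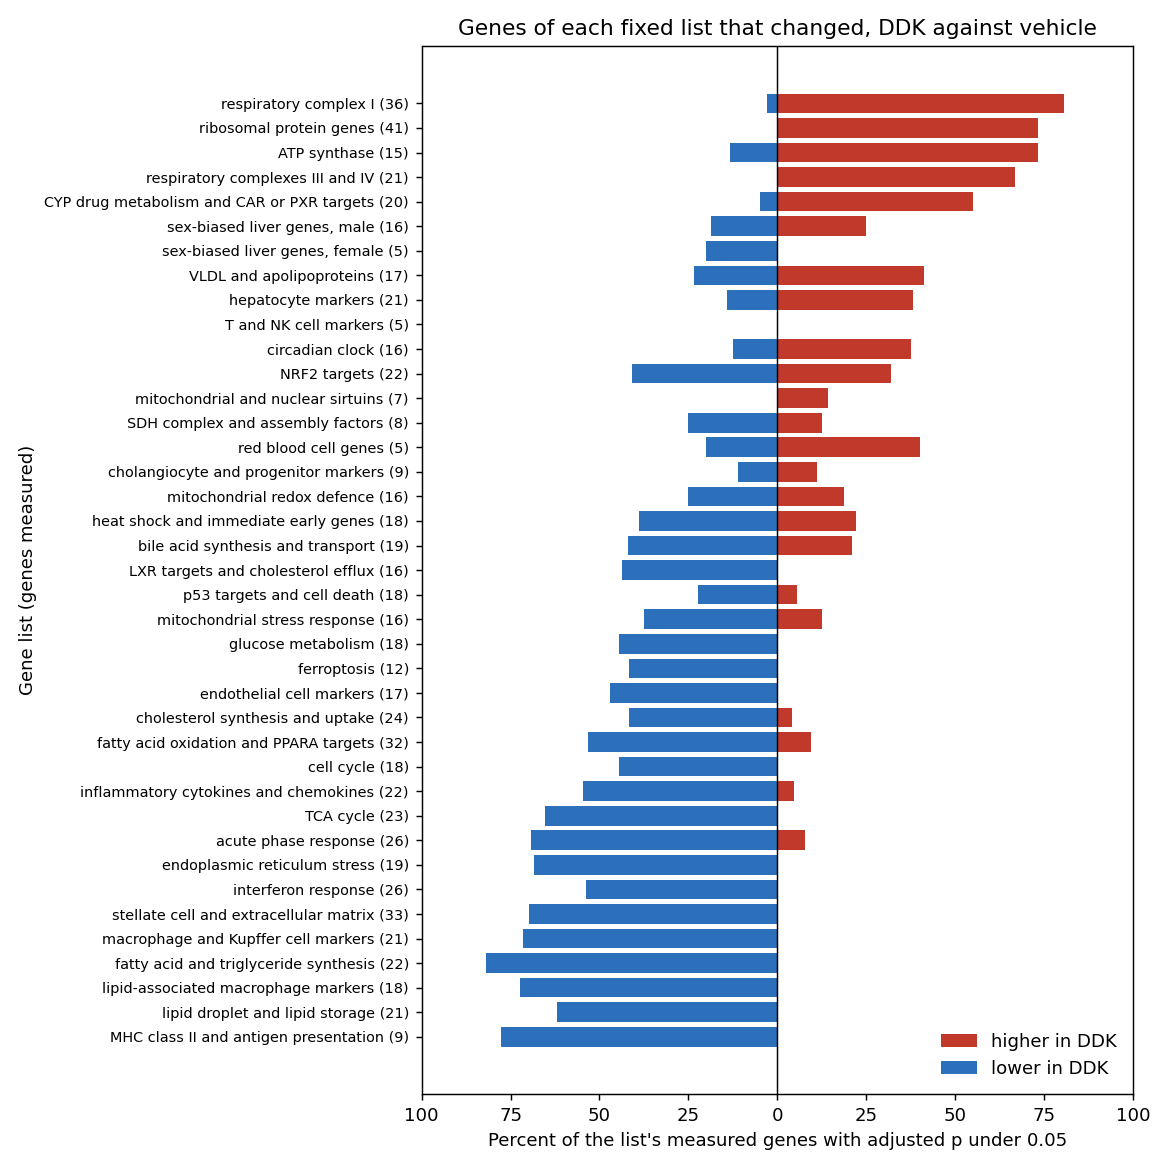
Bars give the percent of each list's measured genes that were higher (red, right) or lower (blue, left) in DDK than vehicle livers at an adjusted p under 0.05 with limma, for the 39 lists tested, with the number measured in brackets. Lists are ordered by their median log2 fold change, from MHC class II at the bottom, with 7 of 9 genes lower, to complex I at the top, with 29 of 36 genes higher.

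For the succinate dehydrogenase complex, which the title names, transcripts of the 4 subunits did not move together. Sdha (chromosome 13, 74322254 to 74350280 on GRCm38) fell from an FPKM of 217 ± 39.2 to 105 ± 8.57 (log2 fold change -1.02 ± 0.16, adjusted p = 0.00184). Sdhb, the iron-sulfur subunit (chromosome 4, 140961203 to 140979193), rose from 229 ± 11.3 to 354 ± 31.1 (0.62 ± 0.13, adjusted p = 0.00551). Sdhd, a membrane anchor (chromosome 9, 50596357 to 50603812), fell from 193 ± 14.7 to 136 ± 26.5 (-0.51 ± 0.16, adjusted p = 0.0274), a call that was lost without a filter (adjusted p = 0.0628), after median-ratio scaling (0.301) and without DDK replicate 1 (0.0816), DDK replicate 2 (0.123), vehicle replicate 2 (0.073) or vehicle replicate 3 (0.0998). Sdhc, the other anchor (chromosome 1, 171127165 to 171150603), stood at 161 ± 13.9 in DDK and 182 ± 8.20 in vehicle (-0.18 ± 0.12, adjusted p = 0.263), and passed only after rescaling to TPM (adjusted p = 0.0283). Sirt3, the main mitochondrial deacetylase (chromosome 7, 140863666 to 140882309), stood at 75.3 ± 9.54 in DDK and 72.9 ± 5.82 in vehicle (0.04 ± 0.14, adjusted p = 0.823). Of the 8 genes of the complex and its assembly factors, 1 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.434). The balance moved with the scaling, with 2 higher and 1 lower after median-ratio scaling, 2 and 2 after quantile normalization, 1 and 3 under TPM and 1 and 4 after length correction. After length correction Sdha (2859 bp) stood at -0.76, Sdhb (1079 bp) at 0.45, Sdhc at -0.24 and Sdhd at -0.57. The gap between Sdha and Sdhb thus narrowed with that correction but stayed. Of 7 sirtuins 1 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.21), Sirt7 by 0.49, while Sirt4 stood at 0.38 ± 0.15 (adjusted p = 0.0615). Sirt4 passed after median-ratio scaling (0.0118), quantile normalization (0.0107) and length correction (0.00978), with library weights (0.0132) and without vehicle replicate 1 (0.0196). In the first 3 of these settings 2 sirtuins rose and 0 fell. Under TPM 0 rose and 2 fell, and Sirt7 lost its call there (0.133), without DDK replicate 2 (0.0771) and without vehicle replicate 2 (0.0536).

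The rest of the respiratory chain stood higher in DDK. Of 36 nuclear-encoded complex I genes, 29 rose and 1 fell (30 and 1 adjusted over the list alone), and their median lay 0.96 above all genes (camera adjusted p = 8.15e-19, adjusted p = 0.335 with an estimated correlation). Ndufa5 rose from an FPKM of 140 ± 32.6 to 404 ± 42.1 (log2 fold change 1.54 ± 0.17, adjusted p = 0.000662), Ndufb4 by 1.37, Ndufa13 by 1.11 and Ndufb5 by 0.72. The member that fell was Ndufs1, the largest subunit (-1.01). Of 21 genes of complexes III and IV, 14 rose and 0 fell (15 and 1 adjusted over the list alone), with Cox6c at 1.11, Cox5b at 1.01, Uqcrb at 0.94 and Cox7b at 0.89 (camera adjusted p = 1.06e-09, adjusted p = 0.335 with an estimated correlation). Of 15 ATP synthase genes 11 rose and 2 fell (11 and 3 adjusted over the list alone), with Atp5j2 at 1.18, Atp5g1 at 1.12, Atp5h at 1.05 and Atp5o at 0.87 (camera adjusted p = 5.61e-06, adjusted p = 0.335 with an estimated correlation). The 2 that fell, Atp5a1 (-0.40) and Atp5b (-0.59), encode the large catalytic-head subunits. Cytosolic ribosomal protein genes rose in the same way, 30 of 41 with 0 lower, the same adjusted over the list alone (camera adjusted p = 1.41e-18, adjusted p = 0.335 with an estimated correlation), among them Rps18 (1.31), Rps27 (1.18), Rpl32 (1.14) and Rpl27 (1.05). These 4 lists hold mainly short genes, and fold change fell with gene length across all genes. The shortest decile of genes (148 to 1229 bp) had a median log2 fold change of 0.32, and the other deciles lay between -0.32 and -0.09. After correction for length, 20 of 36 complex I genes rose and 2 fell (camera adjusted p = 5.01e-06), while the ATP synthase call was lost (adjusted p = 0.0839). Of complexes III and IV 7 genes rose and 1 fell after that correction, and of ribosomal protein genes 18 and 3, with Rps27 no longer past the threshold (adjusted p = 0.0708).

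**Figure D3:**
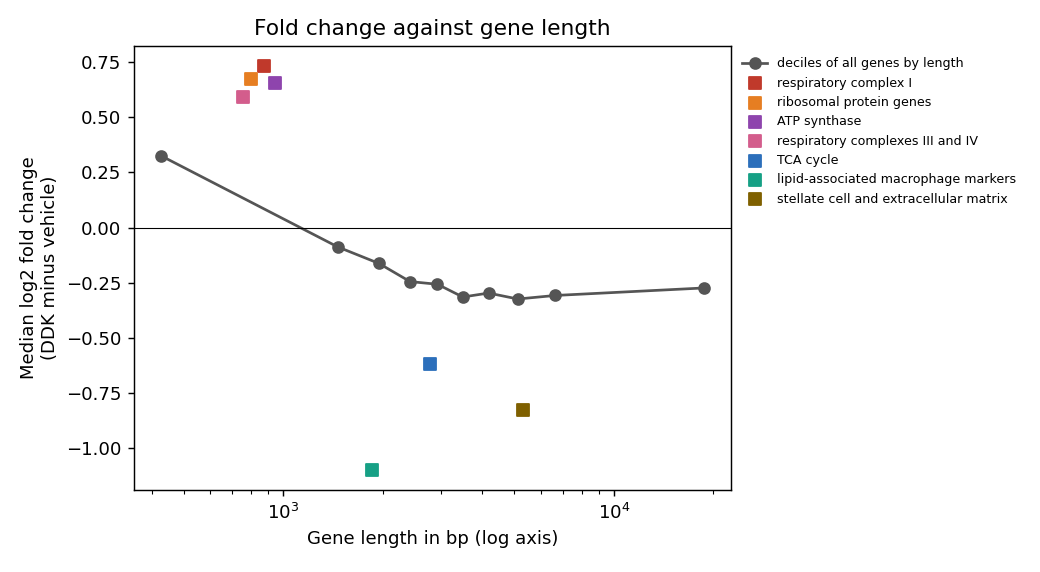
Median log2 fold change (DDK minus vehicle) of each decile of the 10681 genes by length (grey line, log axis in bp, at the geometric mean of the decile's shortest and longest gene), with squares at the median length and median log2 fold change of 7 lists. The shortest decile lay at 0.32, while complex I lay at 0.73 and the tricarboxylic acid cycle list, which includes genes of pyruvate metabolism, at -0.62.

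Genes of the tricarboxylic acid cycle list went down, a list that leaves out the Sdh genes and includes genes of pyruvate metabolism (Pcx, Pdha1, Pdhb, Dlat, Pdk1, Pdk2 and Pdk4). Of 23 measured, 15 fell and 0 rose, the same adjusted over the list alone (median -0.39 relative to all genes, camera adjusted p = 0.00531, adjusted p = 0.335 with an estimated correlation). Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, fell from an FPKM of 39.1 ± 4.52 to 18.5 ± 0.769 (log2 fold change -1.04 ± 0.13, adjusted p = 0.000911). Pyruvate carboxylase, Pcx, fell by 1.19, Dlat by 1.03 and Suclg2 by 0.87. After median-ratio scaling 6 fell and 1 rose. Redox genes were mixed. Of 16 mitochondrial redox defence genes 3 rose and 4 fell (camera adjusted p = 0.773), with Ucp2 (-1.20) and the transhydrogenase gene Nnt (-1.05) lower. Of 22 NRF2 targets 7 rose and 9 fell (8 and 9 adjusted over the list alone, camera adjusted p = 0.0725). Those that rose were mainly glutathione transferases, and heme oxygenase, Hmox1, fell from 27.7 ± 6.76 to 5.46 ± 1.83 (-2.16 ± 0.22). Of 12 ferroptosis genes 5 fell and 0 rose (camera adjusted p = 0.278, and 0.0465 after length correction), including the ferritin receptor gene Ncoa4 (-2.66). Counts for the redox defence and ferroptosis lists were the same adjusted over the list alone. The balance depended on the scaling, with 4 redox defence genes higher and 3 lower after median-ratio scaling and 1 and 10 under TPM, and with 10 NRF2 targets higher and 3 lower after median-ratio scaling and 6 and 11 under TPM.

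Stress genes of the endoplasmic reticulum fell, 13 of 19 with 0 higher, and 15 adjusted over the list alone (median -0.40 relative to all genes, camera adjusted p = 0.00535, adjusted p = 0.612 with an estimated correlation). Hyou1 fell by 1.25, Sdf2l1 from an FPKM of 12.1 ± 0.91 to 5.63 ± 1.29, Atf6 by 0.93 and Pdia4 by 0.89. After median-ratio scaling 8 of these genes fell and 1 rose. Of 16 mitochondrial stress genes 2 rose and 6 fell (camera adjusted p = 0.986), with the hormone gene Fgf21 at -2.06 (adjusted p = 0.053 without a filter) and Clpp at 0.87, and after median-ratio scaling 4 rose and 2 fell. Heat shock and immediate early genes were divided, with 4 of 18 higher and 7 lower (5 and 7 adjusted over the list alone, camera adjusted p = 0.683), Ier2 rising by 2.10 and Hsph1 falling by 1.18. Of 18 cell cycle genes 8 fell and 0 rose, and 9 fell adjusted over the list alone (camera adjusted p = 0.063, and 0.0312 after length correction), with Mcm2 at -0.76 and Mcm5 at -0.70. The cell cycle list holds 34 genes, and the rest lay below the filter. Under TPM 28 passed the filter, 20 of them lower and 0 higher, and after median-ratio scaling 6 of 18 fell and 0 rose. Of 18 genes of p53 and cell death 4 fell and 1 rose, and 2 fell and 0 rose adjusted over the list alone (camera adjusted p = 0.459), with Cdkn1a at -1.57 and Pmaip1 at -0.53, and the counts were 2 and 2 after median-ratio scaling and quantile normalization and 10 lower and 0 higher under TPM. Circadian clock genes lay 0.37 above all genes in median (camera adjusted p = 0.00531, adjusted p = 0.335 with an estimated correlation), 6 of 16 higher and 2 lower, and Dbp rose by 0.87, Per3 by 0.84, Usp2 by 0.62 and Tef by 0.59. Under TPM 2 clock genes rose and 2 fell. Tef lost its call without DDK replicate 1 (0.0659) or 2 (0.0658), and Usp2 without DDK replicate 1 (0.0776) or 2 (0.11) or vehicle replicate 2 (0.0699) or 3 (0.0764). Of 16 male-biased liver genes 4 rose and 3 fell (camera adjusted p = 0.0235, adjusted p = 0.612 with an estimated correlation), with Hsd3b5 at 2.75, Mup3 at 1.22 and Cyp7b1 at 0.75 beside Mup7. That call was lost under 9 other settings, among them median-ratio scaling (adjusted p = 0.141), fry (0.837) and leaving out vehicle replicate 1 (0.151), vehicle replicate 3 (0.109) or DDK replicate 2 (0.0628). Without DDK replicate 1, DDK replicate 2, vehicle replicate 1 or vehicle replicate 3, Hsd3b5 (0.0588 to 0.081) and Cyp7b1 (0.0681 to 0.126) no longer passed. Of 5 female-biased genes 1 fell, Cyp17a1 by 1.18, and 0 rose (camera adjusted p = 0.458). Counts for the mitochondrial stress, clock and sex-biased lists were the same adjusted over the list alone.

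In all, 19 of 39 lists passed camera with the preset correlation, 9 higher and 10 lower, and 0 passed with an estimated correlation. The clock list lost its call too, although its estimate (0.0109) was close to the preset of 0.01. Correlation between genes alone therefore does not account for the loss of calls. By fry, which does not compare a list with other genes, 10 lists that camera did not call were lower, those of mitochondrial redox defence, fatty acid oxidation, cholesterol, LXR targets, glucose, cytokines, endothelium, cell cycle, p53 and ferroptosis (adjusted p from 0.00799 to 0.0421). Fry used the values as deposited, where the median of all genes was -0.23, so lists that moved with all genes can be called lower. The redox defence list lay 0.04 above all genes in median and was still called lower. These fry calls are therefore not evidence of a change beyond that of all genes. At an unadjusted p under 0.05, 5472 genes passed limma's test. Camera also called 9 to 20 lists when the 6 livers were regrouped in the 9 other ways, so a camera call alone does not set the treatment apart from other regroupings. Each regrouping keeps most livers of a treatment on the same side and so holds part of the treatment difference. Its calls are therefore not calls in the absence of a treatment difference. The statistic for the succinate dehydrogenase, mitochondrial redox, mitochondrial stress, bile acid, heat shock, cholangiocyte and red blood cell lists pointed up although their own median log2 fold change was below 0, and for the mitochondrial stress and bile acid lists it differed in sign from the median and mean relative to all genes. The largest decreases not yet described were those of Gna12 (-3.29 ± 0.35), a G protein subunit, Arl1 (-3.21 ± 0.31), a small GTPase of the Golgi, and Ly6d (-2.98 ± 0.21). Gna12 fell from an FPKM of 44.8 ± 21.8 to 3.40 ± 1.35.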

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

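Length correction and voom were chosen after the data were seen. Of the values of named genes under the alternatives, 2466 kept their direction and side of the threshold, 69 lost the call, 8 gained one and 8 changed sign, none of the last past the threshold; of those of called lists, 357 were kept, 41 lost the call and 1 changed sign. The 4327 genes called (1093 higher, 3234 lower) became 767 (205 and 562) at an unadjusted p under 0.05 with a 2-fold change, and 2345 to 5478 with each library left out (599 to 1351 higher, 1711 to 4127 lower), where fewer livers were tested. Higher and lower genes numbered 1931 and 1717 after median-ratio scaling, 1886 and 1743 after quantile normalization, 628 and 5111 after rescaling to TPM, and 1722 and 1844 after length correction, since these move the median of all genes. Of the 4327 genes, 2810 stayed called under median-ratio scaling, 2719 under quantile normalization and 3849 under TPM. Called lists went from 19 to 0 (0 higher, 0 lower) with an estimated correlation. Fry, which does not set a list against all genes, called 20 lists lower. Camera calls were lost with a high estimate (0.684 for ribosomal proteins) and with one near the preset of 0.01 (0.0109 for the circadian clock). For the clock list, camera's adjusted p went from 0.00531 to 0.335 at nearly the same correlation. The loss of all calls therefore does not show that correlation between genes accounts for them. Calls of named genes lost outside the fits that leave out a library were those of Mup7, Sdhd, Fgf21, Apoc1, Alb, Cd24a, Usp2, Hsd3b5, Cyp7b1 and Hba-a1 without a filter, Sirt7, Arg1, Krt7, Tef, Usp2, Cyp7b1 and Hba-a1 under TPM, Sdhd, Cd24a and Alas2 after median-ratio scaling, Alb, Arg1, Cd24a and Alas2 after quantile normalization, Cd24a, Alas2, Hba-a1 and Rps27 after length correction, Mup7 and Hsd3b5 with robust moderation, and Krt7 and Cd24a with voom. Sdhc, which did not pass, stood at 0.114 after median-ratio scaling. Sirt3, which did not pass, stood at -0.193 after TPM, -0.0614 without the 20 most abundant genes, and from -0.0521 (without DDK replicate 1) to 0.126 with each library left out, and at -0.0231 without vehicle replicate 2. With each library left out Nkg7 ranged from -0.00154 (without DDK replicate 1) to 0.691 and Ccl5 from -0.0804 (without vehicle replicate 3) to 0.469, and Ccl5 stood at -0.379 after length correction. Hepatocyte markers stood at -0.0176 relative to all genes after quantile normalization, where the cause was not tested, as for the other sign changes. The replicate block gave 4134 genes (1052 higher, 3082 lower). Equal numbers did not pair the livers, with correlations of their deviations across genes of 0.141, -0.146 and 0.0558. Depth limits low genes, since 3 fragments of a gene of 2000 bp are an FPKM of 0.0415 to 0.0564, and the DDK libraries were the shallower ones.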

Other observations

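Gene families in this paragraph were chosen by symbol after their values were seen. Of the tests below, those of length for the 4 pooled lists and for vehicle replicate 1 were set before their results were seen, and the other tests, the regroupings of livers included, after. All 5 measured Ugt1a genes fell, with a median log2 fold change of -2.33 relative to all genes, and all 5 fell under median-ratio, quantile, TPM and length-corrected values too. They share exons, so they are not independent of each other. Ugt1a6b stood at an FPKM of 0.933 ± 0.558 in DDK and 13.1 ± 5.72 in vehicle (log2 fold change -2.80, limma adjusted p = 0.000682). In the same livers 11 of 20 glutathione transferase genes rose and 1 fell, Gsta3 (-0.67), a split of 8 and 3 under TPM and 14 and 0 under median-ratio scaling. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, rose by 2.28 ± 0.57 and 2.22 ± 0.58 on the log2 scale (adjusted p = 0.0125 and 0.015), with 1 of the 2 past the threshold after length correction. Mt1 stood at 240, 41.1 and 229 in vehicle replicates 1 to 3 and at 684, 890 and 439 in the DDK livers.

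Of 21 measured Mup genes 10 rose and 0 fell, and 9 to 14 rose with 0 lower under the other scalings. Of 12 Cyp2c genes 4 rose and 3 fell, among them Cyp2c54 (1.52) and Cyp2c38 (-0.96). Of 75 mitochondrial ribosomal protein genes 41 were higher and 2 lower (median 0.64 above all genes, with no test of the family), 22 and 6 under TPM and 35 and 3 after length correction. Proteasome genes were divided, 11 of 38 higher and 9 lower, and changed from 14 and 3 under median-ratio scaling to 4 and 13 under TPM. Within the heat shock and immediate early list, Egr1 (1.65), Junb (1.46) and Ier2 rose, while Hspa1b (-2.08), Hspb1 (-1.38) and Hsp90aa1 (-1.22) fell.

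Ribosomal protein and respiratory chain genes were higher in DDK livers, and so were short genes in general (Spearman correlation of fold change with length across genes -0.251, genes not being independent), at a median log2 fold change of 0.29 for 993 genes of the shortest decile outside these lists. Recovery of transcripts by length was set against random lists matched on length and expression. The pooled median of the 4 lists (0.67, against a matched median of 0.42) lay at percentile 100 of 10000. Complex I lay at percentile 100, and the other 3 lists pooled at percentile 99.05. The random lists were drawn gene by gene, while genes of these lists vary together (estimated correlation 0.255 to 0.684). The matched ranges are therefore too narrow, so these percentiles do not decide whether length is the whole cause. Taken alone, complexes III and IV (67.19), ATP synthase (92.16) and ribosomal proteins (94.01) lay inside their matched ranges, so length may account for much of their rise. Scaling stays open in part: 12 of 12 camera calls were kept under 3 scalings, but median-ratio scaling and TPM shift nearly all genes alike, and quantile normalization lowered the lists' medians relative to all genes from 0.96 to 0.67 for complex I, 0.82 to 0.25 for complexes III and IV, 0.88 to 0.42 for ATP synthase and 0.90 to 0.38 for ribosomal proteins. The length trend did not simply follow treatment, since vehicle replicate 1 went with the DDK livers. Deviations were taken from the mean of all 6 libraries and sum to 0, so they show differences between libraries, not which of them carry the trend. The Spearman correlation of a library's deviation with gene length was -0.264 to -0.206 in DDK and -0.173 in vehicle replicate 1. In vehicle replicates 2 and 3 it was 0.328 and 0.331. A treatment effect on these genes stays open as a hypothesis, beside a difference in RNA quality between groups or livers, which was not tested.

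Macrophage genes were lower in DDK livers. A lower share of all non-hepatocyte cells would lower the endothelial, biliary and T or NK cell markers too. The 39 macrophage genes lay lower than those 30 genes by a median log2 difference of -0.77 (-1.02 against -0.25, permutation p = 4e-05 across genes, which are not independent). The compared genes were not matched on expression, and the log2(FPKM + 1) scale understates falls of low genes. This difference therefore does not decide the question, and a lower share of all non-hepatocyte cells stays open. The 33 stellate and matrix genes also lay low, at a median of -0.82 (macrophage minus stellate -0.20, permutation p = 0.197), and with them among the other genes the macrophage genes still lay lower by -0.49 (permutation p = 0.00225), so a lower share of both cell types stays open. Fewer macrophages with unaltered expression cannot be told apart from a change within macrophages, because lipid-associated markers differed from general ones by -0.21 (permutation p = 0.467) and cells were not counted. A fall in macrophages with DDK is therefore a hypothesis.

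Vehicle replicate 1 lay toward the DDK livers, its deviation from the vehicle mean correlating with the DDK effect across genes (r = 0.467, genes not being independent). The deviations of a group sum to 0, so the negative values of vehicle replicates 2 and 3 add nothing, and DDK replicates 1 to 3 stood at 0.0711, 0.317 and -0.289. DDK liver RNA mixed into that library would by itself move risen and fallen genes by the same share. The library's median place between the other vehicle livers (0) and DDK (1) was 0.263 for 298 risen and 0.491 for 842 fallen genes. The difference was -0.23 (permutation p = 1e-04, the smallest that 10000 permutations can give, across genes, which are not independent). A scaling offset of that library would also set these places apart, so the difference does not exclude mixing. Vehicle replicate 1 also shared the direction of the DDK livers in its length trend. For this trend the deviation was taken from the mean of all 6 libraries, not from the vehicle mean. Its Spearman correlation with gene length was -0.173 in vehicle replicate 1, against 0.328 and 0.331 in vehicle replicates 2 and 3. After length correction its correlation with the DDK effect was 0.404, which argues against length as the whole cause. Mixing stays open, and a milder disease state in that mouse, or a difference in sampling, may remain and was not tested.

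The 6 livers allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4327 genes and the highest other split 0, so 1 of 10 splits gave as many. Every other split puts livers of both treatments into a group, so the treatment difference adds to the spread within groups and holds calls down. The 0 of the other splits is therefore no support for the gene calls. For lists, the real split gave 19 and the highest other 20, so 2 of 10 splits gave as many.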
